A study of Mus musculus with 69 samples.

How the data were processed

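Expression was measured in single cells of the dorsal forebrain of mouse embryos at embryonic day 14, each amplified and hybridised to a whole-genome Affymetrix oligonucleotide array. Each sample is 1 cell. The labels put 66 of the 69 cells analysed here in the ventricular and subventricular zones (VZ/SVZ), the layers next to the ventricle where progenitors divide, and 3 in the cortical plate (CP), the outer layer where newborn neurons settle. The source label was used for the group, because the description label of the 3 CP cells names the VZ/SVZ instead. Per the labels' protocols, 102 cells were amplified in the study and 70 were put on arrays, and 1000 copies of lys, 100 of dap, 20 of phe and 5 of thr bacterial RNA were added to each cell as spike controls.

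The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes, with no version given. The scaling applied by the authors is not given in the sources used here. The mean after trimming 2% at either end ranged from 50.1 to 142 over cells, so the cells do not share a trimmed mean. No detection calls were used. The table held 45101 probe sets with values from 0.0058 to 11783, and no pair of cells had identical values. The correlation of log2 values between 2 cells ranged from 0.475 to 0.672.

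Probe sets were named through the platform annotation. Of the 45101 probe sets, 34958 had 1 gene, 932 had several and 9211 had none there. Entrez identifiers of 34754 probe sets were found in the RefSeq gene table of GRCm38.p6, and none of these changed its symbol. Only probe sets with 1 gene were used, and each of the 18194 genes was read from the probe set with the highest mean log2 signal over all 69 cells, chosen blind to group. Differences between cells were taken gene by gene. Mean levels of different probe sets were compared to make this choice and to match random lists.

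The gene lists, the main floor, the rule for naming genes, the clustering and all alternatives but those with the dip floor were fixed before the data were examined. The main floor was the 95th percentile of the TrpnX control probe sets, an RNA that the protocol does not list as added. It came to 6.26, or 2.65 on the log2 scale. Values under it were set to it before log2 was taken. The log2 values of all probe sets had a lower and an upper mode, and this floor lay inside the lower one: 40.1% of values passed it. A second floor was therefore added after seeing the data, at the dip between the modes (49.4, or 5.63 on the log2 scale), which 18% of values and none of the 207 TrpnX values passed. It is called the dip floor, and shares of cells are given at both floors. Where no cell of a group passed the dip floor, the difference from the other group is a bound: the geometric mean of the brighter group over the dip floor, written as at least N-fold, and no fold is given where that is under 1.

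No label names an animal, litter or culture. Each group therefore counts as 1 sample, cells are not replicates, and no p-value, standard error over cells or count of changed genes was computed. Both groups' values are given, with the SD over cells as the spread between cells. Shares of cells carry exact Clopper-Pearson 95% intervals, and differences of shares Newcombe intervals, both of which cover counting error only. There were 25 gene lists. Each list's shift is the median over its members of the difference in mean log2 signal, given with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these cells. Of 324 list genes, 303 had a probe set with 1 gene, and the other 21 are not analysed here. Members are also counted by a difference of at least 1 log2 unit, a rule of size and not a test, chosen after the data were seen.

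The genes named followed a rule: 12 genes higher in CP (above the floor in all 3 CP cells, the lowest of which lay above the VZ/SVZ median), 12 lower (above the floor in at least 50% of VZ/SVZ cells, with the highest CP cell below the VZ/SVZ median), 12 marker genes named in any case, up to 4 members per list with the largest difference, and 8 genes per cluster with the largest positive difference. Genes named outside this rule are said to be so.

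Cells were clustered without labels on a random 50% of the genes outside the lists (seed 1): the 500 genes with the highest SD among those above the floor in 10% to 90% of cells, centred per gene, with each cell scaled to unit length, 10 principal components, Ward linkage and 4 clusters. The list genes and the remaining genes did not enter the clustering and serve as read-outs. A cluster took the name of the fixed marker list (apical progenitor, intermediate progenitor or neuron) with the largest shift in it. No doublet caller was run. The list percentile and the clustering were tested on simulated data made by resampling each gene's VZ/SVZ values. Of 200 unchanged lists, 8% fell outside the central 95%, and all of 100 lists raised by 1 log2 unit in the step for CP against VZ/SVZ, run on 18194 genes, reached percentile 97.5. In the step for the clusters, run on 8945 genes and cut into 3 clusters, 3 classes were planted with 200 genes each raised. A raise of 4 log2 units was recovered with an adjusted Rand index of 1, and with a raise of 2 units the index was 0.015. The raised genes were drawn from both 50% sets of genes, so only some entered the clustering. Raises between 2 and 4 were not tried, and each gene was resampled on its own. The class difference that the clustering of the real cells would miss is thus not known.

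Alternatives were the scaling between cells (75th percentile, quantile normalization, lys and dap spikes), the floor (median of the thr spike, 2 times the main floor, no floor with values under 1 set to 1, and the added dip floor), the mean of all probe sets of a gene, leaving out each CP cell, the clustering settings, and values within letters and numbers of the sample titles that held 6 or more cells. The meaning of these letters and numbers is not given in the sources used here. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.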

Results

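The data are whole-genome expression profiles of 69 single cells from the dorsal forebrain of mouse embryos at embryonic day 14. The VZ/SVZ, which holds dividing progenitors and neurons that have just left the cycle, gave 66 cells, and the CP, where neurons settle, gave 3. Between 3778 and 5812 genes per cell passed the dip floor, with a median of 4774 in VZ/SVZ and 3992 in CP cells. The design asks what single progenitors in the germinal layers express, whether they fall into kinds, and how they differ from cells of the plate. No label names an animal, so each group counts as 1 sample and every difference below describes these cells and has no replicate check.

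The spike RNAs give the spread that amplification and the array add. The lys RNA, at 1000 copies per cell, read 12.65 ± 0.19 on the log2 scale (SD over 69 cells), and dap, at 100 copies, read 11.22 ± 0.59. The phe RNA, at 20 copies, read 9.38 ± 1.01, and all 69 cells passed both floors for these 3 RNAs. The thr RNA, at 5 copies, passed the main floor in 40 of 69 cells (58%, 95% interval 45.5% to 69.8%) and the dip floor in 27 (39.1%, 27.6% to 51.6%). A gene at a few copies per cell can thus be missed in a cell that holds it. In the 3 CP cells phe read 8.50 ± 0.90 against 9.42 ± 1.0 in VZ/SVZ cells, and thr 2.77 ± 0.22 against 5.15 ± 2.91.

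**Figure D1:**
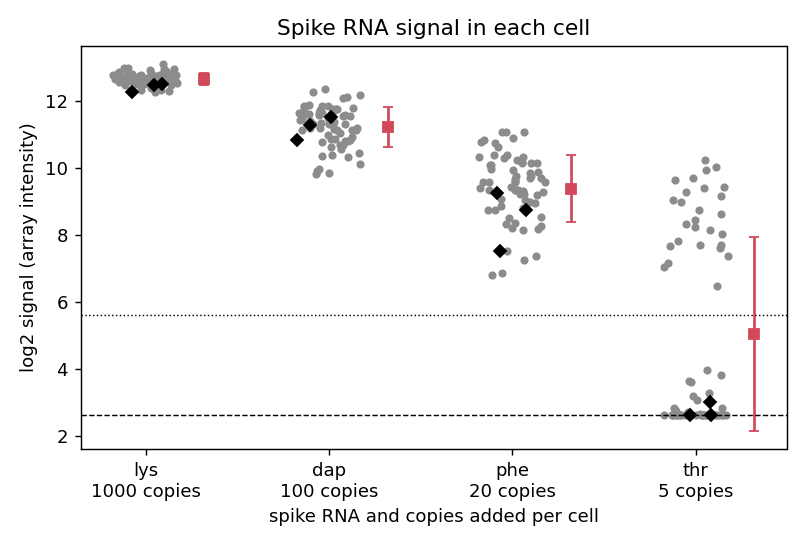
Log2 signal (vertical axis) of the 4 spike RNAs (horizontal axis, with the copies added per cell) in each of the 69 cells; grey circles are VZ/SVZ cells, black diamonds CP cells, red squares and bars the mean and SD over cells, the dashed line the main floor and the dotted line the dip floor. The SD over cells widens from 0.19 for lys to 2.89 for thr.

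CP cells held genes of neurons and had lower signal for most genes of dividing progenitors. Stmn2, a microtubule regulator of growing axons, read 11.95 in CP against 4.42 ± 3.46 in VZ/SVZ cells, and Bcl11b, a transcription factor of deep-layer neurons, 11.57 against 5.02 ± 3.35. Mki67, a marker of proliferating cells, passed the dip floor in none of the 3 CP cells and in 83.3% of VZ/SVZ cells (72.1% to 91.4%), a difference of at least 20.5-fold. Pax6 and Sox2, transcription factors of apical progenitors (radial glia), were at least 11.8-fold and at least 6.76-fold lower in CP.

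Among the neuron markers, 23 of 27 were higher in CP by at least 1 log2 unit and 1 was lower. The list's median difference was 3.68 on the log2 scale, above all 10000 matched random lists, whose mean was −0.62. Stmn2 was higher by 7.53, Bcl11b by 6.56, Mapt, which encodes the microtubule protein tau, by 6.18 and Ina, an intermediate filament of neurons, by 5.20. Tbr1, a transcription factor of early cortical neurons, read 9.98 in CP and 4.84 ± 3.04 in VZ/SVZ cells. Tubb3 and Dcx, which encode a neuronal tubulin and a microtubule protein of migrating neurons, read 11.29 and 10.53 in CP against 6.79 ± 3.80 and 7.05 ± 3.73.

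The other genes highest in CP by the fixed rule were Shtn1, Ndrg1, Lrfn5, Sh3gl2, Cabp7, Lpl, Hspa12a, Ptpro and Clmp, with differences between 6.33 and 7.04 on the log2 scale, and Hs3st4, for which only a bound is given. Such sizes depend on the floor and the probe sets. Over the alternatives Lrfn5 ranged from 4.08 to 9.02 and Cabp7 from 3.36 to 8.37. Shtn1 encodes shootin, a protein of axon formation, and passed the dip floor in 12.1% of VZ/SVZ cells (5.38% to 22.5%). Lrfn5, a synaptic adhesion molecule, did so in 3.03% (0.368% to 10.5%) and Sh3gl2, an endophilin of synaptic vesicle recycling, in 13.6% (6.43% to 24.3%). Hs3st4, a heparan sulfate sulfotransferase, passed it in all 3 CP cells and in 0 of 66 VZ/SVZ cells, which is compatible with a share of up to 5.44%, and its CP level was at least 14.5-fold above the dip floor.

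The apical progenitor markers were lower in CP: 27 of 28 by at least 1 log2 unit, with a median of −3.86, below all 10000 matched random lists (mean −0.85). Lhx2, a selector gene of the cortex, read 11.13 ± 0.996 in VZ/SVZ cells, where it passed the dip floor in all 66, the 13 neuron-like ones described below included, and in none of the CP cells, a difference of at least 45.5-fold. Fabp7, the brain lipid-binding protein of radial glia, was at least 39.8-fold and Aldoc, a glycolytic aldolase of glial cells, at least 10.3-fold lower. The Notch effectors Hes1 and Hes5 read 2.77 and 3.49 in CP and 4.43 ± 2.46 and 5.23 ± 2.47 in VZ/SVZ cells, and no fold is given since the VZ/SVZ means lay under the dip floor.

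Of the cell cycle genes, the G2/M list was the lowest and the S phase list less so. All 23 G2/M genes were lower in CP by at least 1 log2 unit (median −5.99, below all matched random lists, mean −0.997), as were 18 of 22 S phase genes (median −2.66, below all, mean −0.56). Cks2, a subunit of mitotic kinases, Ube2c and Cdc20, of the complex that ends mitosis, and Top2a, a topoisomerase of dividing cells, were at least 37.6-fold, 37.2-fold, 22.6-fold and 31.1-fold lower. Of the S phase genes, Mcm3, Mcm6 and Mcm2, of the replicative helicase, were at least 5.93-fold, 5.22-fold and 5.10-fold lower, and Rrm1, of ribonucleotide synthesis, read 4.47 against 10.08 ± 2.29. Not all were low: the helicase gene Mcm7 and the G1 kinase gene Cdk4, picked after their values were seen, passed the dip floor in all 3 CP cells, at 9.62 and 10.08 against 10.80 ± 2.13 and 11.32 ± 0.67. Among cell cycle exit and CDK regulators 12 of 16 were lower (median −2.32, percentile 0.18), with the G1 genes Ccnd2 and Cdk6 at least 19.5-fold and 15.1-fold lower, followed by Rbl1 and Cdkn2c at least 4.597-fold and 3.26-fold lower.

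Intermediate progenitor markers differed less as a list: 12 of 22 were lower by at least 1 log2 unit, 2 were higher, and the median was −1.34 (percentile 3.51, mean of random lists −0.51). Neurog2, a proneural factor, was at least 11.04-fold lower in CP, and Eomes, the T-box factor of intermediate progenitors, at least 1.55-fold. Tead2 read 4.54 against 9.60 ± 2.32, Btg2, an antiproliferative gene, 3.79 against 7.18 ± 3.05, and Pcdh8 was at least 1.35-fold lower. Neurod1 read 2.76 in CP and 4.41 ± 2.99 in VZ/SVZ cells, with no CP cell and 25.8% of VZ/SVZ cells above the dip floor.

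The remaining genes lowest in CP were Pou3f3, a POU factor of the upper cortical lineage, its neighbouring noncoding RNA gene Pantr1, the translation factor gene Eif1b and Tmpo, of the nuclear lamina. They were at least 89.8-fold, 59.5-fold, 47.3-fold and 33.6-fold lower, and Pou3f3 and Pantr1 passed the dip floor in all 66 VZ/SVZ cells. Cortical area and dorsal identity genes had a median of −2.90 (percentile 0, 7 of 11 lower), with Gli3 at least 9.35-fold lower and Nr2f1 at 4.75 against 10.63 ± 0.94. Microcephaly genes had a median of −2.00 (percentile 0.21, 7 of 9 lower and 1 higher), with Aspm at least 7.35-fold, Stil at least 1.69-fold and Cep152 at least 1.34-fold lower.

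Signalling lists were lower too, against VZ/SVZ cells most of which were progenitor-like. Against the 13 neuron-like VZ/SVZ cells described below, the FGF-ERK, Wnt and Notch medians were nearer 0, at −0.17, −0.46 and −0.47. The values that follow are against all VZ/SVZ cells. FGF-ERK response genes had a median of −1.77 (percentile 0.26, 5 of 10 lower), with Fgfr3 at least 5.29-fold lower and Fgfr1, Etv5 and Fgfr2 at 4.37, 4.78 and 4.40 against 8.89 ± 2.21, 8.32 ± 3.59 and 7.42 ± 2.85. Wnt targets and effectors had a median of −1.53 (percentile 0.47, 8 of 12 lower), with Fzd8 at least 5.62-fold, Ccnd1 at least 2.72-fold and Tcf7l1 at least 1.38-fold lower. The Notch list had 12 of 18 members lower, Notch1 by at least 7.92-fold and Notch2 and Nrarp by at least 3.47-fold each, yet its median of −1.23 lay at percentile 16.2 of random lists (mean −0.68). Apical junction genes were similar, with a median of −1.31 at percentile 16.8 (7 of 12 lower, 1 higher): Prom1 was at least 8.23-fold lower and Ctnna1 read 4.46 against 10.13 ± 2.25.

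Migration and cytoskeleton genes had a median of −0.19 (percentile 86.1), with 3 members higher and 6 of 17 lower: Cdk5r1 and Dab1 were higher by 3.85 and 3.69, and Nde1, a centrosome gene, was at least 8.89-fold lower. Glycolysis genes lay at −0.76 (percentile 50.8; Pfkl at least 1.01-fold lower) and housekeeping genes at −0.22 (percentile 87.2). Immediate early genes lay at −0.13 (percentile 25.7), though Jun was at least 2.37-fold lower, p53 response genes at −0.11 (percentile 44), and the 4 sex-linked genes at −0.54 (percentile 16.9).

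Markers of other cell types differed little between the groups at the main floor. With no floor, their medians ranged from −0.58 for oligodendrocyte precursor to 0.26 for erythroid markers. Leaving out 1 CP cell moved the endothelial median to between −0.08 and 0.20. The values that follow are at the main floor with all cells. Medians were −0.06 for interneuron lineage, −0.05 for Cajal-Retzius, 0.08 for endothelial, −0.01 for microglia, 0.00 for erythroid, −0.05 for pericyte and meningeal and −0.07 for oligodendrocyte precursor markers, at percentiles between 24.4 and 86.8. No CP cell passed the dip floor for Gad1, Cdh5, Csf1r, Hba-x, Col1a2 or Olig2, and at most 3.03% of VZ/SVZ cells did (0.368% to 10.5%). These genes are examples and not all members were as low in VZ/SVZ cells. Sp8 of the interneuron list was lower in CP by at least 1 log2 unit. Ebf3 and Reln of the Cajal-Retzius list were 1.27 and 1.13 higher in the intermediate-progenitor-like cells described below.

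**Figure D2:**
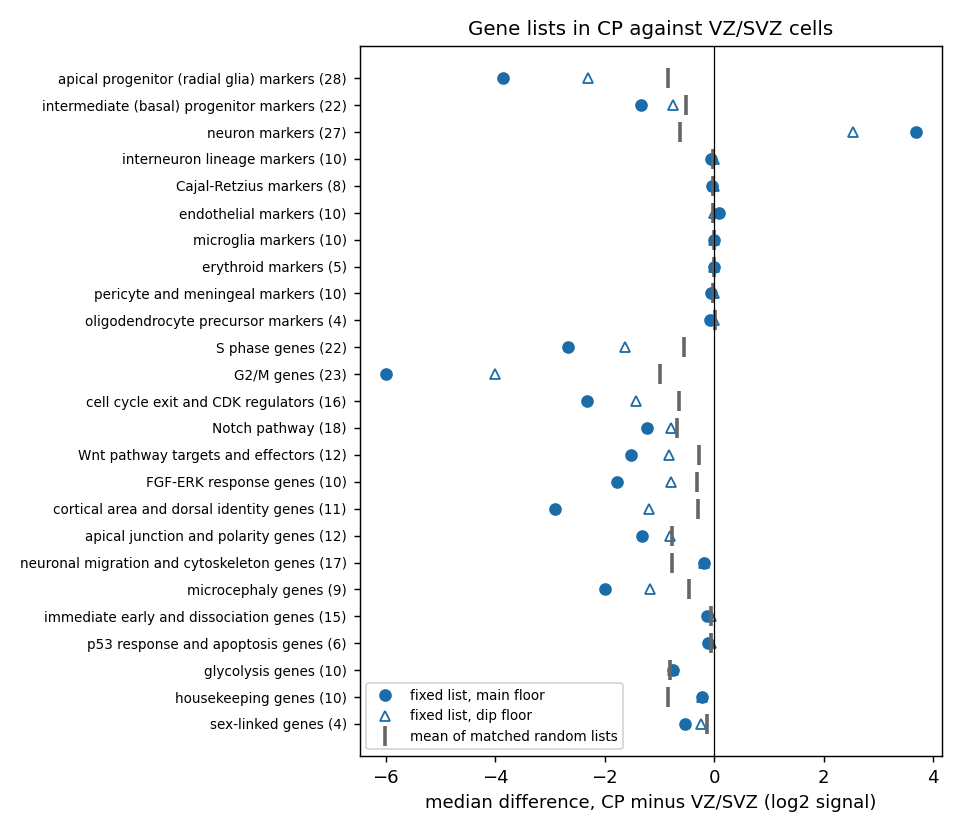
Median difference in log2 signal, CP minus VZ/SVZ (horizontal axis), for each fixed gene list (vertical axis, measured members in parentheses); filled circles use the main floor, open triangles the dip floor and grey bars mark the mean of 10000 matched random lists. The neuron list lies at 3.68 and the G2/M list at −5.99, and the 7 lists of other cell types lie near 0.

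The named genes kept their direction under other floors and probe sets, while sizes moved. At the dip floor all 35 genes tried kept their sign and 23 moved by over 1.5 times; the difference became 5.20 for Stmn2, and the list medians 2.53 for neuron, −2.31 for apical progenitor and −3.999 for G2/M genes. With the mean of all probe sets, 14 moved by over 1.5 times, among them Hspa12a (1.58) and Dcx (0.79) and, with values under the floor set to it, Pax6 (−1.69), Top2a (−2.72), Tmpo (−2.48) and Pou3f3 (−4.31). Over all genes, most of them near the floor, the median difference was −0.05. Over genes whose mean over all cells passed the dip floor, a choice that favours genes high in VZ/SVZ, it was −0.94, and −0.30 with quantile normalization, so list medians are to be read against their random lists. Of the lists, leaving out 1 CP cell moved intermediate progenitor markers to between −1.99 and −0.74, the Notch list to between −2.03 and −0.93, microcephaly genes to between −3.40 and −1.27 and migration genes to between −0.56 and 0.06. With the mean of all probe sets, FGF-ERK genes stood at −0.58, Wnt genes at −0.84, area genes at −1.35, apical junction genes at −0.70, intermediate progenitor markers at −0.67 and CDK regulators at −1.45. At the dip floor these 6 lists stood at −0.79, −0.83, −1.19, −0.81, −0.76 and −1.44, S phase genes at −1.63, Notch genes at −0.79, microcephaly genes at −1.17 and sex-linked genes at −0.23. Glycolysis genes stood at −0.30 with quantile normalization. Lists near 0 changed sign under some settings: immediate early genes ranged from −0.18 to 0.52, p53 response genes from −0.21 to 0.45, migration genes from −0.56 to 0.21 and housekeeping genes from −0.36 to 0.07.

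Within the VZ/SVZ, Pax6, Sox2, Neurog2 and Mki67 passed the dip floor in most cells, and Hes1, Hes5, Eomes, Neurod1 and Tbr1 in under 50%. Pax6 passed the dip floor in 57 of 66 cells (86.4%, 75.7% to 93.6%), Sox2 in 49 (74.2%, 62% to 84.2%), Mki67 in 55 (83.3%, 72.1% to 91.4%) and Neurog2 in 53 (80.3%, 68.7% to 89.1%). Eomes passed it in 28 (42.4%, 30.3% to 55.2%) and Btg2 in 45 (68.2%, 55.6% to 79.1%). Of the neuronal genes, Dcx did so in 39 (59.1%, 46.3% to 71.1%), Tubb3 in 35 (53%, 40.3% to 65.4%), Tbr1 in 23 (34.8%, 23.5% to 47.6%) and Neurod1 in 17 (25.8%, 15.8% to 38%). Hes5 passed it in 29 cells (43.9%, 31.7% to 56.7%) and Hes1 in 19 (28.8%, 18.3% to 41.3%). At the main floor the shares were 89.4% for Pax6, 78.8% for Sox2, 87.9% for Mki67, 93.9% for Neurog2, 69.7% for Eomes, 81.8% for Btg2, 68.2% for Dcx, 71.2% for Tubb3, 40.9% for Tbr1, 33.3% for Neurod1, 80.3% for Hes5 and 59.1% for Hes1.

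Over all VZ/SVZ cells, those with Eomes held Gadd45g, Neurod1, Neurod6 and Mki67 more often and Hes1 less often at both floors. For several other genes the difference depended on the floor, and within title letter X several were smaller or turned. At the dip floor Gadd45g, a stress and growth arrest gene, was found in 24 of 28 Eomes cells and 4 of 38 others, a difference of 75.2 percentage points (53.3 to 85.9). Hes1 was found in 2 of 28 and 17 of 38, a difference of −37.6 points (−54 to −16.3), Slc1a3, a glutamate transporter of radial glia, differed by −37.2 points (−55.8 to −12.8) and Hes5 by −26.7 points (−46.4 to −2.53). Neurod1 (42.1 points, 20.5 to 60.2), Hes6 (33.3, 13.7 to 49.4), Dll1 (31.8, 7.58 to 51.5), Btg2 (24.2, 1.496 to 42.9), Neurog2 (21.8, 2.23 to 38.4) and Insm1 (17.5, 0.175 to 33.1) were found more often with Eomes. So were the neuronal genes Dcx and Neurod6 (46.2 points each, 22.9 to 62.6) and the cycle genes Mki67 (22.7, 4.62 to 38.7) and Top2a (20.1, 2.39 to 35.9). The cells without Eomes include most of the neuron-like VZ/SVZ cells described below, of which 3 of 13 passed the dip floor for Eomes. Mki67 and Top2a passed it in 3 and 4 of these 13, so their gaps do not measure a difference among progenitors.

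Pax6 was found in 27 of 28 Eomes cells and 30 of 38 others, as was Insm1 (17.5 points, 0.175 to 33.1). The same limit holds for Pax6, which passed the dip floor in 4 of the 13 neuron-like VZ/SVZ cells. For the other genes tried, the interval of the difference spanned 0: Sox2 was found in 21 of 28 and 28 of 38 (1.32 points, −20.3 to 21.3), and the progenitor genes Vim and Nes differed by 12.2 (−4.20 to 27.1) and −14.8 points (−36.6 to 8.34). The neuronal genes Tubb3 and Tbr1 differed by 13.3 (−10.6 to 35) and 13.9 points (−8.83 to 35.6). At the main floor, where 46 of 66 cells counted as holding Eomes, Gadd45g differed by 51.7 points (25.8 to 67.9) and Hes1 by −30 (−48.3 to −4.32), but Neurog2 by 5.65 (−6.83 to 26), Insm1 by 1.30, Dll1 by 4.78 and Dcx by 11.7. Slc1a3 (−16.3, −36.2 to 9.15), Btg2 (9.78, −9.19 to 33), Hes6 (11.3, −5.36 to 33.5) and Top2a (7.83, −3.83 to 28) spanned 0 there, and Neurod1 differed by 26.3 (1.56 to 43.7). Tubb3 differed by 37.6 points there (12.9 to 58.5), and Hes5 turned to 22 points more (0.878 to 44.7). Neurod6 (31.1, 6.01 to 52.7), Mki67 (25.7, 7.15 to 47.8) and Vim (15, 2.56 to 36) were also found more often with Eomes there. Within title letter X the main floor gave −6.82 points for Hes1, −5 for Neurog2, −6.82 for Btg2, −10.9 for Insm1, 1.82 for Neurod1 and 27.7 for Gadd45g. The dip floor gave −18.5 for Hes1, 5.43 for Hes5, −20.7 for Neurog2, −2.72 for Btg2, 33.2 for Neurod1, 32.6 for Gadd45g and −8.15 for Pax6 there.

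Clustering without labels gave 4 clusters, of which clusters 1 and 4 were apical-progenitor-like (27 and 8 cells), cluster 2 intermediate-progenitor-like (18) and cluster 3 neuron-like (16, including all 3 CP cells). Of the 66 VZ/SVZ cells, 53% were apical-progenitor-like (40.3% to 65.4%), 27.3% intermediate-progenitor-like (17% to 39.6%) and 19.7% neuron-like (10.9% to 31.3%). These shares followed the sample titles: all 7 cells under letter A were apical-progenitor-like, all 7 under C intermediate-progenitor-like and all 7 VZ/SVZ cells under D neuron-like. Letter B held 4, 9 and 1 cells of the 3 classes and letter X 24, 2 and 5. With 3, 5 or 6 clusters, which cut the same tree, every cell kept its class, and with the other random set of genes 64 of 69 did. The 4 clusters were less stable than the classes. With other genes, linkage, scaling or floors, their adjusted Rand index with the main run ranged from 0.589 to 0.731. For the classes it ranged from 0.785 to 0.890. The stability of the split between clusters 1 and 4 was not measured on its own.

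Apical-progenitor-like cells held the radial glia list 4.37 log2 units above the other cells at the median, with 26 of 28 markers higher by at least 1, and the neuron list at −2.25. Within title letter B, which holds all 3 classes, these were 2.15 and −0.52. The held-out genes that led cluster 1 were Ednrb, the endothelin B receptor, at 9.85 ± 1.02 (5.97 above the other cells), Rgcc, a cell cycle regulator (5.53), Zfp36l1, an mRNA decay factor (5.34), Id4, an inhibitor of bHLH factors (4.92), Wwtr1, the Hippo pathway coactivator TAZ (4.73), the helicase gene Pif1 (4.70), Add3 (4.64) and Mfge8 (4.57). Pax6 and Sox2 passed the dip floor in all 35 cells of clusters 1 and 4. FGF-ERK and Wnt lists were higher in this class by 2.46 and 1.67 (both at percentile 100), with Fgfr3 5.53 and Fzd8 5.13 higher. Glycolysis genes were 0.69 higher (percentile 93.5), led by Slc2a1 (2.99) and Hk2 (2.24).

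Of the lists, S phase and G2/M genes differed most between clusters 4 and 1. S phase genes averaged 10.29 ± 0.56 per cell in cluster 4 and 7.63 ± 1.66 in cluster 1 (SD over cells of the list's median), and G2/M genes 9.30 ± 2.42 and 11.10 ± 0.32. The median member differed by 2.07 and −1.81, while the apical progenitor list differed by 0.14. The p53 response list differed by 0.62, with Ccng1, a p53 target, at 7.70 ± 3.18 and 5.09 ± 2.86, and 7 of 22 intermediate progenitor markers and 5 of 18 Notch genes were lower in cluster 4 by at least 1 log2 unit. Genes leading cluster 4 against all other cells, not against cluster 1 alone, were Dusp16, a MAP kinase phosphatase (4.87), Ccn1, a matrix protein (4.85), Evc, a ciliary gene (4.73), the replication genes Gins2 (4.28), Atad2 (4.25) and Dtl (4.09), Tnfaip8 (4.27) and Jun (4.21). Jun, an immediate early gene that handling can induce, read 10.41 ± 0.40 there, but was also 3.68 higher in cluster 1 than in all other cells. The immediate early list as a whole lay at −0.04 in cluster 4 (percentile 29.9).

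Intermediate-progenitor-like cells held their list 2.01 units above the other cells, with 19 of 22 markers higher by at least 1 and 1 lower. Within title letter B this shift was 0.91. Eomes read 10.92 ± 0.78 (6.51 higher), Gadd45g 10.06 ± 1.32 (6.001), Mfng, a glycosyltransferase that modifies Notch, 10.12 ± 0.75 (5.795), Neurog2 11.95 ± 0.35 (4.21) and the somatostatin receptor gene Sstr2 8.03 ± 2.85 (3.95), and Eomes passed the dip floor in all 18 cells. Afap1 (4.70), Coro1c (3.89), an actin regulator, and Nsg2 (3.87), a neuronal endosome protein, completed the leading genes. S phase and G2/M lists were higher by 1.39 and 1.31 (both at percentile 100) than in the other cells, which include the neuron-like ones. Against cluster 1 the G2/M list was lower (9.83 ± 2.63 and 11.10 ± 0.32), and within title letter B its shift was −0.0404. The apical progenitor list stood at −1.68 at the median, with Ednrb at −4.68 and Id4 at −3.91, while Pax6 still read 9.15 ± 1.56. Hes1 and Hes5 passed the dip floor in 1 and 2 of 18 cells, FGF-ERK genes had a median of −1.24 (percentile 0) and glycolysis genes −0.99 (percentile 0.01), with Slc2a1 at −1.73 and Aldoa at −1.68. Neuron markers were split, 8 of 27 higher and 6 lower, with Neurod1 3.64 and Dcx 3.19 higher and Gap43 at −3.19.

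Neuron-like cells held the neuron list 3.78 units above the others, with 24 of 27 markers higher by at least 1 and none lower. Stmn2 (7.92), Ank3, of the axon initial segment (6.34), Bcl11b (6.12), Nuak1, a kinase of axon branching (6.10), Abcc8 (5.999), Nfasc, a neuronal adhesion molecule (5.92), Tubb3 (5.83) and Cdk5r1, the activator of Cdk5 (5.78), led the held-out genes. Tbr1 passed the dip floor in all 16 cells at 9.12 ± 1.05. At the median, apical progenitor markers stood at −4.57, G2/M genes at −6.19 and S phase genes at −2.95. With the dip floor, apical progenitor, neuron and S phase lists stood at −2.60, 2.22 and −1.43, and within title letter X S phase genes stood at −1.95. The medians of the lists of the other 7 cell types lay within 0.10 of 0 in every class. The Cajal-Retzius list reached percentile 99.6 in intermediate-progenitor-like cells, with Ebf3 1.27 and Reln 1.13 higher, and Sp8 of the interneuron list was 1.504 higher in apical-progenitor-like cells.

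**Figure D3:**
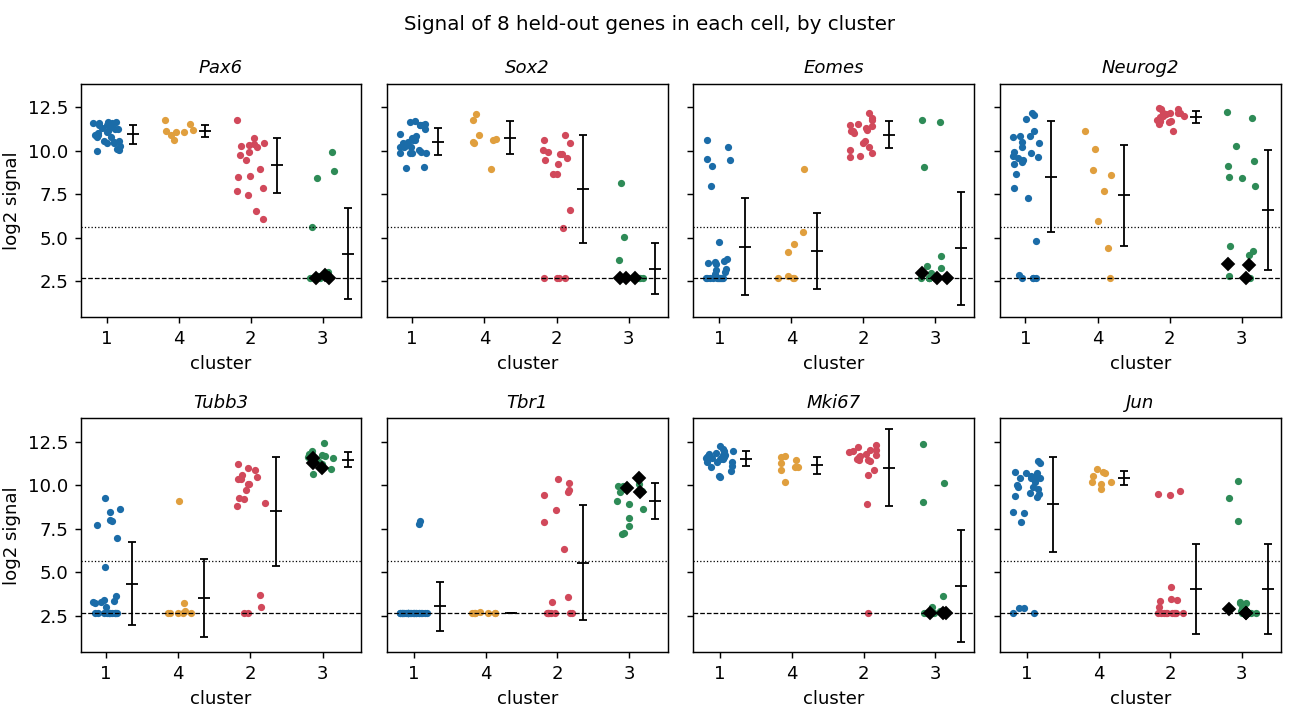
Log2 signal (vertical axis) of 8 genes that did not enter the clustering, in each cell by cluster (horizontal axis; clusters 1 and 4 apical-progenitor-like, 2 intermediate-progenitor-like, 3 neuron-like); circles are VZ/SVZ cells, black diamonds CP cells, bars the mean and SD over cells, the dashed line the main floor and the dotted line the dip floor. Eomes lies at 10.92 ± 0.78 in cluster 2, and Tubb3 at 11.47 ± 0.43 in cluster 3.

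**Figure D4:**
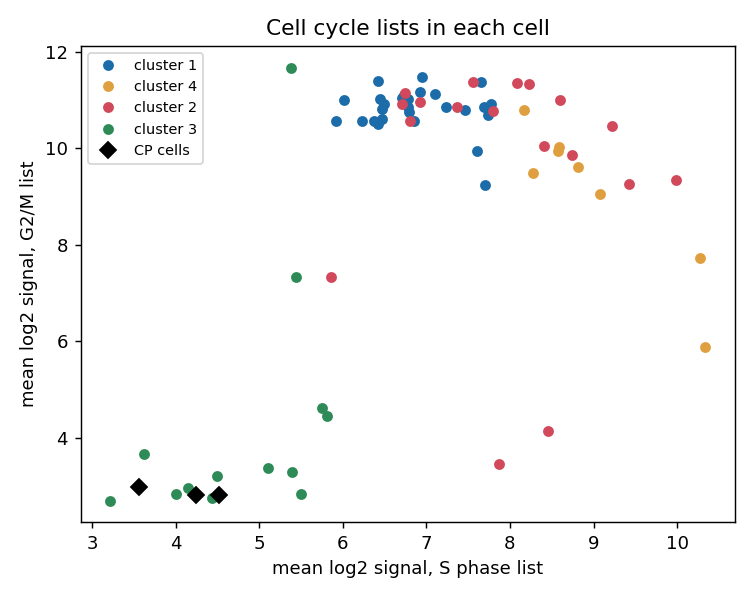
Mean log2 signal of the S phase list (horizontal axis) against the G2/M list (vertical axis) in each cell; colours give the cluster and black diamonds the 3 CP cells. Cluster 1 cells lie high on the G2/M axis, cluster 4 cells lie to the right on the S phase axis, and the CP cells lie low on both.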

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

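Of the alternatives, the dip floor, and letter X at the dip floor for co-detection, were chosen after seeing the data. CP list shifts stayed within 1 SD over cells of their value in 264 alternatives and moved in 11, all in lists near 0 or among immediate early genes. This SD spans progenitors and neurons and is wide for many lists. It was 2.96 for intermediate progenitor markers, whose change from −1.34 to −0.67 counts as stayed. A list can thus change greatly or turn sign and still count as stayed, so the count is no measure of robustness. Single genes in CP against VZ/SVZ stayed within 1 SD in 339 and moved in 46, and none changed sign. Class counts stayed inside the 95% counting interval of their share in all 30; they ranged from 35 to 38 apical-progenitor-like, 14 to 21 intermediate-progenitor-like and 13 to 18 neuron-like cells, and 63 to 69 cells kept their class. Shares of cells with a marker moved in 72 and stayed in 84, so they depend on the floor and the titles. Where a value below moved, the cause was not tested.

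With no floor, shifts were −0.21 for interneuron, 0.21 for Cajal-Retzius, −0.056 for microglia, 0.26 for erythroid, −0.41 for pericyte and meningeal, −0.58 for oligodendrocyte precursor and 0.52 for immediate early genes. The Cajal-Retzius shift was 0.0013 with the floor at the thr median, 0 at the dip floor and −0.067 to −0.011 without each CP cell; the microglia shift was 0.0077 with 75th percentile scaling.

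At the dip floor, shares were 28.8% for Hes1, 43.9% for Hes5, 42.4% for Eomes, 80.3% for Neurog2, 68.2% for Btg2, 53% for Tubb3 and 39.1% for the thr spike. Co-detection with Eomes was 31.8 points for Dll1, 75.2 for Gadd45g, −37.2 for Slc1a3, 46.2 for Dcx and, reversed, −26.7 for Hes5. Apical markers were 3.23 in apical-progenitor-like cells, and apical, neuron and S phase lists −2.60, 2.22 and −1.43 in neuron-like cells.

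At 2 times the main floor, shares were 34.8% for Hes1, 48.5% for Hes5, 51.5% for Eomes and 56.1% for Tubb3; co-detection was 70.0 points for Gadd45g, 5.70 for Tubb3 and, reversed, −21.1 for Hes5; neuron-like cells had apical and S phase lists at −3.90 and −2.37. With the mean of all probe sets, Hes5 was at 62.1% and Btg2 at 92.4%; with that of the spikes, dap read 7.88, phe 7.93 and thr passed in 72.5%.

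The following shares of cells with a gene are at the main floor. Within title letter A, shares were 100% for Pax6, Sox2, Hes1, Hes5 and Mki67, 42.9% for Eomes, 57.1% for Neurog2 and 0% for Neurod1 and Tbr1, and the apical-, intermediate-progenitor-like and neuron-like shares 100%, 0% and 0%. Within B they were 100% for Pax6, Neurog2, Btg2 and Mki67, 28.6% for Hes1, 92.9% for Eomes and Dcx, 64.3% for Neurod1, and 28.6%, 64.3% and 7.14% for the classes. In B, apical-progenitor-like cells had apical, neuron and G2/M lists at 2.15, −0.52 and 1.95, and intermediate-progenitor-like cells their list at 0.91 and, reversed, G2/M at −0.0404. Within C they were 100% for Pax6, Hes5, Eomes, Neurog2, Tubb3 and Dcx, 57.1% for Sox2, 14.3% for Hes1, 71.4% for Neurod1 and 85.7% for Tbr1, and 0%, 100% and 0% for the classes. Within D they were 0% for Pax6 and Sox2, 42.9% for Hes1 and Eomes, 28.6% for Hes5 and Mki67, 57.1% for Btg2, 100% for Neurog2, Tubb3, Dcx and Tbr1, and 0%, 0% and 100% for the classes. Within X they were 100% for Pax6, 93.5% for Sox2, 77.4% for Hes1, 19.4% for Neurod1, 58.1% for Tubb3, 41.9% for Dcx and 25.8% for Tbr1, 77.4% and 6.45% for the progenitor classes, 0 points for Vim with Eomes, and −1.95 for S phase genes in neuron-like cells. Within X at the dip floor, co-detection with Eomes was −20.7 points for Neurog2, 43.5 for Hes6, −8.15 for Pax6, −40.8 for Slc1a3, −37 for Nes, 2.72 for Tubb3 and 40.8 for Dcx. At the main floor, within number 15 shares were 100% for Pax6, Sox2, Hes5 and Mki67, 71.4% for Hes1, 57.1% for Eomes, 0% for Neurod1 and Tbr1, and 100%, 0% and 0% for the classes, and lys read 12.85. Within number 16 they were 100% for Pax6, Sox2, Hes5 and Mki67, 85.7% for Eomes, 57.1% for Tubb3, Tbr1 and intermediate-progenitor-like cells, and 0% for neuron-like cells. At the dip floor, Hes1 and Hes5 passed in 0 of 7 cells of C and of D, Eomes in 0 of 7 of A and of D, and Neurog2 in 1 of 7 of A.

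Signal over background limits what absence means: the thr spike, at 5 copies, passed the dip floor in 39.1% of cells. No paired analysis was possible because the labels pair no cells, and no title letter or number held both CP and VZ/SVZ cells.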

Other observations

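The comparison of CP cells with neuron-like VZ/SVZ cells, the sex of the title numbers and all tests below except that of RNA from a cell of the other sex were chosen after results had been seen. Set against the 13 neuron-like VZ/SVZ cells, and among the list genes and the genes named above only, Pou3f3, Pantr1 and Lhx2 were at least 80.7-fold, 46.4-fold and 35-fold lower in the 3 CP cells and passed the dip floor in all 13 others, and Lpl, a lipoprotein lipase gene, was at least 25.8-fold higher in CP. Few title numbers stand behind these values: 2 of the 3 CP cells shared number 19, and 5 of the 13 neuron-like VZ/SVZ cells number 18. Several lists lay nearer 0 in this comparison than against all VZ/SVZ cells. Medians were −0.47 for apical progenitor, −0.15 for S phase, −0.17 for FGF-ERK, −0.46 for Wnt, −0.59 for microcephaly and −0.79 for area genes. The shifts against all VZ/SVZ cells thus depend on the mix of classes there. The CP cells had the neuron list at −0.02 but differed within it. Ina, Mapt, Fezf2, a factor of deep-layer neurons, and Mef2c were higher in CP by 3.53, 3.40, 3.22 and 3.01, and Gria2, a glutamate receptor subunit, differed by −1.80; Neurod1 passed the dip floor in 0 of 3 CP and 6 of 13 neuron-like cells. Intermediate progenitor markers had a median of −1.61, with 15 of 22 lower by at least 1 log2 unit; their mean level was 7.88 to 8.33 in 3 of the 13 neuron-like cells, 5.26 to 6.69 in the others and 3.62 to 5.004 in CP. The netrin receptor gene Unc5d was at least 8.54-fold, Pcdh8 at least 3.12-fold and Neurog2 at least 3.37-fold lower, and Insm1 stood at −3.91. Migration genes had a median of −0.93, with Nrp1, a semaphorin receptor, at least 5.48-fold and Cdk5 at least 3.34-fold lower, while Dab1 was 2.64 higher. G2/M genes had a median of −1.21 and were uneven among the neuron-like cells: their mean level was 11.67 and 7.34 in 2 cells and between 2.70 and 4.63 in the others, against 2.82 to 2.99 in CP, and Ube2c passed the dip floor in 4 of 13. These genes were picked after their values were seen.

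Title letters followed the clusters. Letters B and X each held cells of all 3 classes, so the letter alone did not set the class. Handling of the cells under each letter, as the maker of the neuron-like class, was tested within letter X. The neuron list was 3.89 higher there in 5 neuron-like than in 26 other cells (SD over the former 0.562). The class was named by this list, so that outcome was nearly fixed in advance and decides nothing. For the intermediate-progenitor-like class handling stays open too: within letter B its list was 0.91 higher in 9 than in 5 other cells, under the bound of 1. That the letters name classes given by the submitters cannot be told apart from other meanings, since pairs of cells with the same letter correlated at 0.636 and pairs with the same number at 0.629, a difference of 0.0068 against an SD of 0.0564; pairs sharing neither correlated at 0.590. No biological explanation was tested.

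Intermediate-progenitor-like cells held apical and neuronal genes side by side, and no biological explanation was tested. An apical and a neuron-like cell picked into 1 sample would hold at most the sum of both cells' signal; in 3 measures tried in turn, the intermediate progenitor list lay 1.47 above the higher of the other class means, 0 of 18 cells passed the 95th percentile of 560 such sums, and the cells' mean lay 0.676 above the mean of 10000 sets of 18 sums (SD over sets 0.231). The bound, the highest set, was not passed and 25 sets reached the cells' level, so these sums do not decide. The sums include 3 neuron-like cells with the list at 7.88 to 8.33, which raises their level. Eomes passed the dip floor in all 18 cells and in 35.5% of sums. As a leading gene of the class it decides nothing alone. If signals add, a mix of both cells would also hold at least the apical cell's signal. The apical progenitor list averaged 5.95 ± 1.98 in the 18 cells and 10.23 ± 0.45 in apical-progenitor-like cells (SD over cells of the list's median). These values argue against such a mix for the 18 cells as a set. In 1 of them the list's mean was 8.59, near the lowest apical-progenitor-like cell at 8.72. RNA of a cell of the other sex stays open. Of the 18 cells, 1 had both Xist and a Y-linked gene, which met the bound set before. That bound was wrong, because cells of 1 title number never differed in sex and a second cell from the same number would not show.

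Apical-progenitor-like cells fell into 2 clusters that differed in cell cycle genes. Whether the yield of amplified RNA was lower in 1 of the clusters stays open: thr differed by −3.09 in cluster 4 against cluster 1, against a larger SD over cells of 2.98. The other spikes went the other way, by 0.06 for lys, 0.24 for dap and 0.11 for phe, each less than its SD over cells. A lower yield alone would not raise 1 list and lower another. In cluster 4, 17 of 22 S phase genes were higher by at least 1 log2 unit and 0 lower. Of 23 G2/M genes, 14 were lower and 0 higher, while housekeeping genes differed by 0.12. These values argue against yield as the only source of the cell cycle difference. No biological explanation was tested.

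Xist, expressed from the inactive X chromosome, passed the dip floor without Y-linked Eif2s3y, Kdm5d or Uty in 46 cells, and a Y-linked gene did so without Xist in 19; 1 cell had both and 3 neither. All 3 CP cells were among those with Xist alone, and the VZ/SVZ held 43 such cells and all 19 with a Y-linked gene alone, so these came from at least 2 embryos. Of 16 title numbers with 2 or more such cells, 0 mixed the sexes, against a mean of 10.5 and a lowest count of 5 in 10000 shuffles of the cells. As a hypothesis, each title number marks cells of 1 embryo; numbers that each mark cells of several embryos of the same sex were not excluded.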
